A study of Mus musculus with 12 samples.

How the data were processed

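Liver RNA of C57BL/6 mice was sequenced in 12 libraries, 4 each from mice on a normal fat diet (NFD), on a high fat diet (HFD) and on a high fat diet with N-acetylcysteine in the drinking water (NAC_HFD). Groups and replicate numbers were taken from the sample labels alone. Per the submitters' processing notes, the tools fastp, HISAT and RSEM were used with genome build GRCm38; their versions, settings and the step each served are not given in the sources used here. Total RNA was extracted and treated with DNase I per the labels.

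The deposited gene table and the deposited tables of mRNA and lncRNA transcripts hold TPM, a share of transcripts with a fixed total, for each library, made by the authors. TPM divides by transcript length and by the library's total, so the tables keep no read depth. The depth of each library is therefore unknown, no counting interval or detection floor was given, and a value of 0 was reported as listed at 0. The mRNA and lncRNA transcripts of a library together had a fixed sum, and all 19252 genes of the gene table equalled the sum of their mRNA and lncRNA transcripts within 0.1 TPM or 1 percent. A rise of a few abundant transcripts thus lowers every other value in the library. The authors' deposited comparison tables hold fold changes as ratios, log2 fold changes, p-values and adjusted p-values per the file headers, for HFD against NFD and for NAC_HFD against HFD; the tool and the test behind them are not given in the sources used here. In those tables every listed p-value was under 0.05 and every log2 fold change at least 1 in size, which was checked on the files. Values from them are named as the authors' deposited table wherever they are printed, and no fit here used them.

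Genes with TPM of at least 1 in at least 4 of the 12 libraries were tested (11376 of 19252). Their values were put on the scale log2(TPM + 1). For lncRNA transcripts the floor was 0.1 TPM in at least 4 libraries (25205 of 52170 transcripts; 11700 were listed at 0 in all 12 libraries) and the scale was log2(TPM + 0.1). Fold changes are differences of group means on these scales; the pseudocount makes them smaller than the ratio of mean TPM where a gene is low. One linear model with 3 group means was fitted to all 12 libraries with limma 3.58.1 (lmFit, then eBayes with trend and robust) in R 4.3.3, with 9 residual degrees of freedom per gene before moderation. Tests were two-sided, and p-values were adjusted by Benjamini and Hochberg within each comparison and each table, with a threshold of 0.05. These p-values measure the difference against the spread between these 12 samples. The 53634 mRNA transcripts served only to check the gene table.

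Gene lists were fixed from general knowledge before the data were examined: 23 lists of liver functions and 16 lists of cell type markers. The 33 lists with at least 3 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation and fry, which asks whether a list's own genes move one way on balance, were run beside it. Markers of T and NK cells (2 tested members), B and plasma cells (0), neutrophils (2), exocrine pancreas (1) and skeletal muscle (1) were too few to test, and a list of sex chromosome genes served only to check the animals' sex. Counts "adjusted over the list alone" use Benjamini and Hochberg within 1 list.

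The named genes follow a rule written before the data were examined. It takes, per comparison, the 6 highest and 6 lowest log2 fold changes among genes past the threshold whose groups do not overlap, leaving out predicted and clone-named genes; where no gene passes, it takes those among the 50 smallest unadjusted p, named as not passing. It adds a fixed panel of 32 genes of lipid, bile acid, redox and inflammatory function (29 of them tested), up to 4 members with the smallest p of each list, the 4 highest and 4 lowest lncRNA transcripts past the threshold with groups that do not overlap, and the 2 largest and 2 smallest fold changes of each of the authors' deposited comparison tables. Non-overlap means that each library of one group lies above each library of the other; chance gives this for 2.86% of genes. Gene positions are those of the annotation of build GRCm38 and were found for 95.4% of tested genes. Some named genes (Cyp2, Cyp4a, Mup, Gstm, Hspa1b and Raet1e families) have close paralogs, and how the authors divided reads between paralogs is not given in the sources used here. The lncRNA that the series title names was not analysed here.

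A comparison of single values per library used an exact two-sided permutation test, whose smallest possible p with 4 against 4 libraries is 0.0286. The diet and N-acetylcysteine comparisons share the HFD libraries, which alone gives a negative covariance of their fold changes; its size was taken from the residual variance, from 100 simulations with no effect, and from splits of the HFD libraries 2 and 2. The comparisons of HFD and of NAC_HFD with NFD share the NFD libraries and were treated in the same way. KEGG pathways named in the gene table were tested by a one-sided Fisher's exact test against the 4779 tested genes with a pathway, a choice made after the data were seen.

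The fit was tested on simulated data with the group sizes, spread and floor of these tables. With 100 genes shifted on the log2 scale by 0.5 and 100 by 1, limma found 48% and 93%, with 3 false calls among 144. For lncRNA transcripts a shift of 1 was found in 3% and a shift of 3 in 72%, with 1 false call among 76. That rate may not hold for transcripts listed at 0 in a whole group, as many called ones were. A list shifted by 0.5 was called by camera with either correlation and by fry, and no other of the 31 simulated lists was. The simulated genes were independent, while the estimated correlation was 0.593 for the interferon list and 0.765 for Kupffer cell markers. The simulation thus cannot tell how often camera with the preset correlation calls lists by chance here.

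Alternatives tried were other pseudocounts, other floors or none, median-of-ratios scaling, quantile normalization, a block for replicate number, array weights, a fold change minimum, only the 8 libraries of the comparison, and leaving out each library in turn. Chosen after the data were seen were gene TPM rescaled to the same sum within the gene table, and lncRNA transcripts above 0 in all 12 libraries. The labels do not say that replicate numbers pair animals, and 3 of 12 libraries correlated best with a library of their own number, so the main test is unpaired. The 32 columns of single libraries in the authors' deposited comparison tables were not used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.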

Results

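The data comprise 12 liver RNA libraries from C57BL/6 mice in 3 groups of 4. One group received a normal fat diet (NFD), one a high fat diet (HFD) and one the high fat diet with 2 g of N-acetylcysteine per litre of drinking water (NAC_HFD). N-acetylcysteine is a cysteine precursor used to raise glutathione, the main thiol antioxidant of the cell. Feeding lasted 14 weeks, and the labels give an age of 8 weeks without saying at which point it was taken. The design asks what the high fat diet does to liver RNA, mRNA and lncRNA alike, and what N-acetylcysteine does to animals on that diet. Values are TPM made by the authors, given below as mean ± SD with n = 4 per group, and fold changes are limma estimates on the log2(TPM + 1) scale with their standard error. Positions are those of build GRCm38, given from start to end of the gene, and the genes of the gene table named with a position are annotated as protein coding.

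The depth of the libraries is unknown, because TPM keeps no read counts. In the gene table, between 10864 and 11316 genes per library reached 1 TPM, with means of 11093 ± 121 in NFD, 11195 ± 92.5 in HFD and 10938 ± 94.0 in NAC_HFD. Between 21341 and 23313 lncRNA transcripts per library reached 0.1 TPM. A single assembled transcript, MSTRG.6188.1, took 23.5% to 29.6% of the TPM of a library, and mitochondrially encoded genes took 8.91% to 12.6% of the gene table. Within each group the mean correlation of a library with the others, across genes on the log2 scale, was 0.978 to 0.989; genes are not independent replicates. The Y-linked genes Ddx3y (11.8 to 19.5 TPM) and Eif2s3y (18.7 to 33.6 TPM) were present in all 12 libraries.

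Liver RNA of HFD and NFD animals differed in single genes of lipid uptake and storage, of the interferon response and, in both directions, of the cytochrome P450 family. Cd36, a fatty acid transporter, was at 63.3 ± 16.2 TPM in HFD and 16.0 ± 4.03 TPM in NFD (log2 fold change 1.91, SE 0.33, adjusted p = 0.0161). Mogat1, a monoacylglycerol acyltransferase, rose from 0.283 ± 0.104 to 2.90 ± 1.22 TPM (1.55, SE 0.21, adjusted p = 0.0028), and Fitm1, a protein of lipid droplet formation, from 12.5 ± 4.15 to 32.8 ± 4.71 TPM (1.37, SE 0.24, adjusted p = 0.0119). Lgals1, which encodes the sugar-binding protein galectin-1, rose from 3.46 ± 1.40 to 25.8 ± 6.99 TPM (2.61, SE 0.36, adjusted p = 0.00554). In each of these 4 genes all 4 HFD libraries lay above all 4 NFD libraries.

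With limma, 316 of 11376 genes passed an adjusted p of 0.05, 249 higher and 67 lower in HFD, and 308 of the 316 had groups that did not overlap. Across all tested genes 12.4% did not overlap, against 2.86% by chance. The 6 largest rises were in Cyp2b9 (ENSMUSG00000040660, chromosome 7, 26173350 to 26210661), Cfd (ENSMUSG00000061780, chromosome 10, 79890853 to 79892655) and Lgals1 (ENSMUSG00000068220, chromosome 15, 78926725 to 78930465), followed by other genes. These were Cyp2a22 (ENSMUSG00000091867, chromosome 7, 26931631 to 26939413), Adgrv1 (ENSMUSG00000069170, chromosome 13, 81095068 to 81633391) and Fbf1 (ENSMUSG00000020776, chromosome 11, 116142285 to 116168271). Cyp2b9, a cytochrome P450 higher in female than in male mouse liver, was at 0.508 ± 0.483 TPM in NFD and 62.9 ± 34.9 TPM in HFD (5.24, SE 0.77, adjusted p = 0.0102), with HFD libraries from 20.5 to 99.3 TPM. Cfd, the complement protease adipsin that fat cells secrete, was at 0.200 ± 0.255 and 12.2 ± 13.7 TPM (3.03, SE 0.55, adjusted p = 0.0200); the HFD library of replicate 4 was at 32.7 TPM. Adgrv1, an adhesion receptor, rose by 2.38 (SE 0.21, adjusted p = 8.99e-05), Cyp2a22, a cytochrome P450, by 2.57 (SE 0.56, adjusted p = 0.0417) and Fbf1, a protein of the cilium base, by 1.94 (SE 0.32, adjusted p = 0.0112).

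The 6 largest falls were in Cyp2c69 (ENSMUSG00000092008, chromosome 19, 39842660 to 39886769), Igfbp2 (ENSMUSG00000039323, chromosome 1, 72824480 to 72852474), Adgrf1 (ENSMUSG00000041293, chromosome 17, 43270283 to 43325876), followed by other genes. These were Raet1e (ENSMUSG00000053219, chromosome 10, 22158542 to 22189697), Cib3 (ENSMUSG00000074240, chromosome 8, 72204335 to 72213086) and Cyp2c40 (ENSMUSG00000025004, chromosome 19, 39767073 to 39812814). Cyp2c69, a cytochrome P450, fell from 2.40 ± 0.479 to 0.218 ± 0.0780 TPM (log2 fold change -1.47, SE 0.12, adjusted p = 8.99e-05). Igfbp2, which encodes a binding protein of insulin-like growth factors, fell from 329.6 ± 120 to 131.7 ± 38.6 TPM (-1.28, SE 0.26, adjusted p = 0.0234). Adgrf1, an adhesion receptor, fell by 1.21 (SE 0.20, adjusted p = 0.00958), and Raet1e, a ligand of a natural killer cell receptor, by 1.17 (SE 0.27, adjusted p = 0.0379). Cib3, a calcium-binding protein, and Cyp2c40 fell by 1.16 each (SE 0.18 and 0.21, adjusted p = 0.00553 and 0.0131). The Cyp2, Cyp4a and Raet1e families have close paralogs, between which reads can be shared. Leaving out single libraries changed some of these calls. That of Raet1e was lost without any 1 of the 8 libraries (highest adjusted p = 0.118, without HFD replicate 4), that of Cyp2a22 without 7 of them (0.128, without HFD replicate 1). That of Igfbp2 was lost without 5 (highest adjusted p = 0.0752, without HFD replicate 1) and that of Cyp2c40 without HFD replicate 4 (0.0508). The total count was 142 without NFD replicate 1, 90 without HFD replicate 1, 129 without HFD replicate 2 and 97 without HFD replicate 4.

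**Figure D1:**
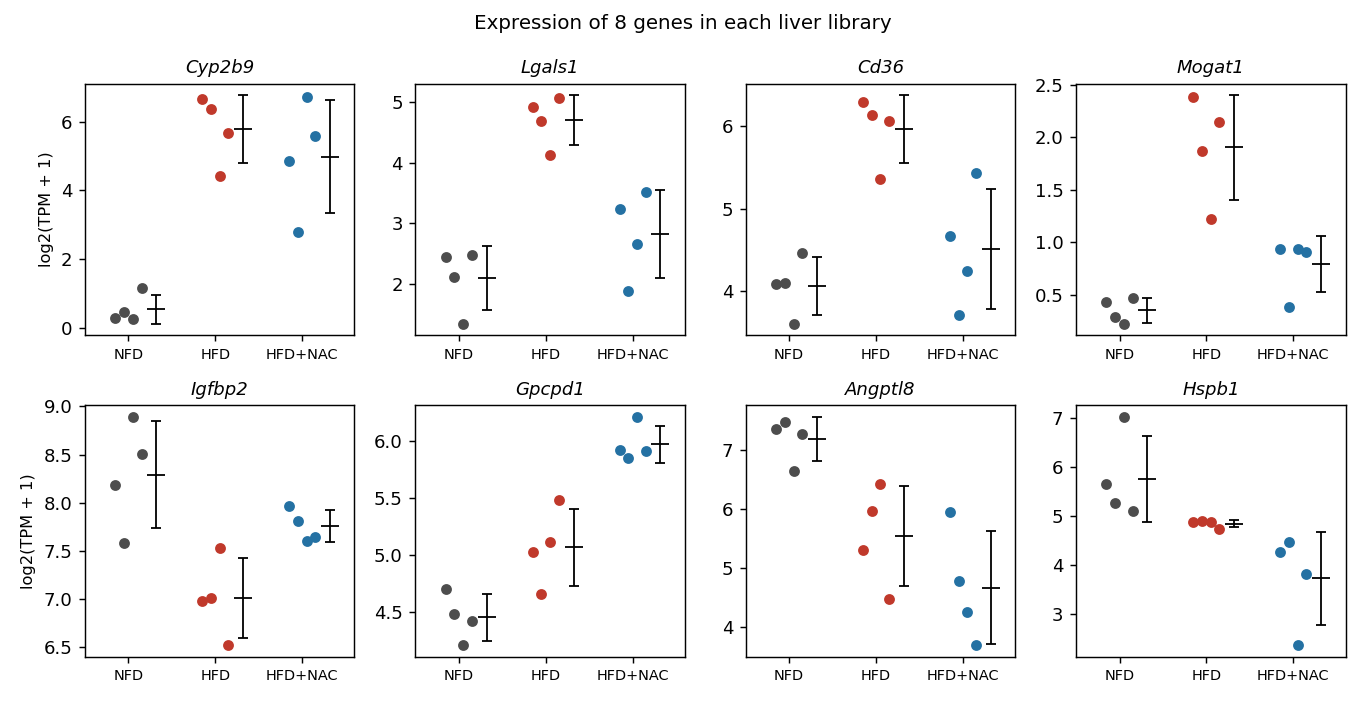
TPM of 8 named genes in each of the 12 libraries on the log2(TPM + 1) scale, with points for libraries and black marks for the mean ± SD of the 4 libraries of a group. Cyp2b9, Lgals1, Cd36 and Mogat1 had all 4 HFD points above all 4 NFD points, and Hspb1 and Angptl8 had all 4 NAC_HFD points below all 4 NFD points.

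By list, interferon response genes were higher in HFD: all 26 tested members had a positive fold change, with a median of 0.63. Camera gave an adjusted p = 2.82e-10 with the preset correlation and an adjusted p = 0.643 with an estimated correlation, so the call was lost with the latter. Of the 26, 3 rose past the threshold over all genes and 17 when adjusted over the list alone. They were Zbp1, a sensor of unusual nucleic acids (4.05 ± 0.883 to 11.6 ± 5.20 TPM, adjusted p = 0.0141), and Psmb8, a subunit of the immunoproteasome (12.9 ± 2.89 to 21.4 ± 3.95 TPM, adjusted p = 0.0235). The third was the guanylate-binding protein Gbp2 (1.58 ± 0.278 to 4.22 ± 1.66 TPM, adjusted p = 0.0321). The calls of Psmb8 and Gbp2 were lost without 4 and 6 of the 8 libraries (highest adjusted p = 0.0851 without HFD replicate 1 and 0.102 without HFD replicate 4). As the mean of the list per library, HFD was at 3.98, 3.41, 3.14 and 3.44 and NFD at 2.49, 2.58, 3.34 and 2.97 (difference 0.65, exact permutation p = 0.0571).

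Markers of Kupffer cells, the resident macrophages of the liver, moved with the interferon genes. All 14 had a positive fold change in HFD (median 0.55; camera adjusted p = 9.33e-04, and adjusted p = 0.747 with an estimated correlation). None passed alone, over all genes or adjusted over the list alone. Among them Clec4f was at 18.5 ± 4.31 TPM in NFD and 27.8 ± 8.06 TPM in HFD, and Cd5l at 23.2 ± 6.64 and 39.2 ± 17.1 TPM. The call was lost without HFD replicate 4 (adjusted p = 0.0585), and the list mean per library overlapped (difference 0.50, exact permutation p = 0.143). Acute phase and inflammation genes were called higher (median 0.27; adjusted p = 0.00837, and adjusted p = 0.747 with an estimated correlation). Of their 26 members 2 rose, Saa3, an acute phase protein (6.82 ± 2.07 to 17.9 ± 6.01 TPM, adjusted p = 0.0158), and Vcam1, a cell adhesion molecule (3.50 ± 0.0548 to 7.31 ± 2.37 TPM, adjusted p = 0.0307), and 3 when adjusted over the list alone. This list's call was lost without HFD replicate 1 or HFD replicate 4 (highest adjusted p = 0.265). The call of Saa3 was lost without HFD replicate 4 (0.0515) and that of Vcam1 without 7 of 8 libraries (highest 0.0955, without HFD replicate 4). Saa1 was at 1936 TPM in HFD replicate 4 and at 38.1 to 119 TPM in the other HFD libraries. The list of macrophages derived from monocytes was not called (adjusted p = 0.0985). Of its members 1 rose over all genes and 3 adjusted over the list alone. That 1 was Plac8 (2.42 ± 0.807 to 5.33 ± 1.11 TPM, adjusted p = 0.0185; 0.0705 without HFD replicate 1, and also lost without HFD replicate 2).

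Lipid droplet and fatty acid uptake genes were called higher (25 members, 20 positive, median 0.25; adjusted p = 0.00244, and adjusted p = 0.643 with an estimated correlation). Cd36, Mogat1 and Fitm1 made up the 3 that rose over all genes, and 5 rose when adjusted over the list alone. Without HFD replicate 1 or HFD replicate 4 the call of Cd36 was lost (highest adjusted p = 0.0631). Plin2, which coats lipid droplets, was at 178 ± 71.3 and 223 ± 52.8 TPM (adjusted p = 0.546), Cidec at 5.71 ± 6.56 and 10.6 ± 3.40 TPM (adjusted p = 0.314). Fatty acid oxidation genes and PPARalpha targets were called higher (29 members, 24 positive, median 0.25; adjusted p = 0.00266, and adjusted p = 0.747 with an estimated correlation). Over all genes 2 rose, Vnn1, a pantetheinase (34.2 ± 8.83 to 75.2 ± 11.6 TPM, adjusted p = 0.0248), and Pdk4, a kinase that restrains pyruvate oxidation (1.11 ± 0.304 to 2.19 ± 0.544 TPM, adjusted p = 0.0465). Adjusted over the list alone 5 rose and 2 fell. The list call was lost without NFD replicate 2 (adjusted p = 0.178), and those of Vnn1 and Pdk4 without 5 and 7 of 8 libraries (highest 0.0876 and 0.150, each without HFD replicate 1). The omega-hydroxylases Cyp4a10 and Cyp4a14, also on that list, had negative fold changes of -0.44 and -0.85 (adjusted p = 0.437 and 0.374). Adipose tissue markers were called higher on 3 tested members (median 0.56; adjusted p = 0.00837, and adjusted p = 0.432 with an estimated correlation). Cfd was the 1 that rose over all genes and all 3 rose when adjusted over the list alone. Pck1 and Adipor2, the other two, are also expressed by hepatocytes. A floor of 5 TPM left too few adipose markers to test.

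Ribosomal protein genes were lower in HFD in 26 of 27 members (median -0.29; adjusted p = 3.74e-09, and adjusted p = 0.643 with an estimated correlation). In limma 0 passed over all genes and 5 fell when adjusted over the list alone. The list means per library overlapped, with NFD at 7.47, 7.53, 7.504 and 7.03 and HFD at 7.003 to 7.19 (exact permutation p = 0.114). NFD replicate 4 also had the highest mitochondrial share, 12.6%, and the highest lncRNA TPM, 395100. Rps18 was at 265.9 ± 25.4 TPM in NFD and 206.5 ± 20.6 TPM in HFD (adjusted p = 0.0861). Heat shock genes were lower in 14 of 15 members (median -0.28; adjusted p = 2.28e-04, and adjusted p = 0.643 with an estimated correlation). In limma 0 passed over all genes, and 1, the chaperone Hsph1, fell when adjusted over the list alone (116.3 ± 17.5 to 77.97 ± 4.18 TPM, adjusted p = 0.0631 over all genes). Male-biased liver genes were called lower (17 of 22 negative, median -0.44; adjusted p = 0.00244, and adjusted p = 0.747 with an estimated correlation). In limma 0 members passed either way, and the list call was lost without HFD replicate 1 or HFD replicate 2 (highest adjusted p = 0.116). The list mean per library was 7.14, 7.48, 8.43 and 8.38 in HFD and 8.11 to 8.43 in NFD (exact permutation p = 0.371). Female-biased genes were not called (adjusted p = 0.859), and their median of 0.38 was opposite in sign to the camera test; Cyp2b9 rose while Cyp2c69 and Cyp2c40 fell.

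**Figure D2:**
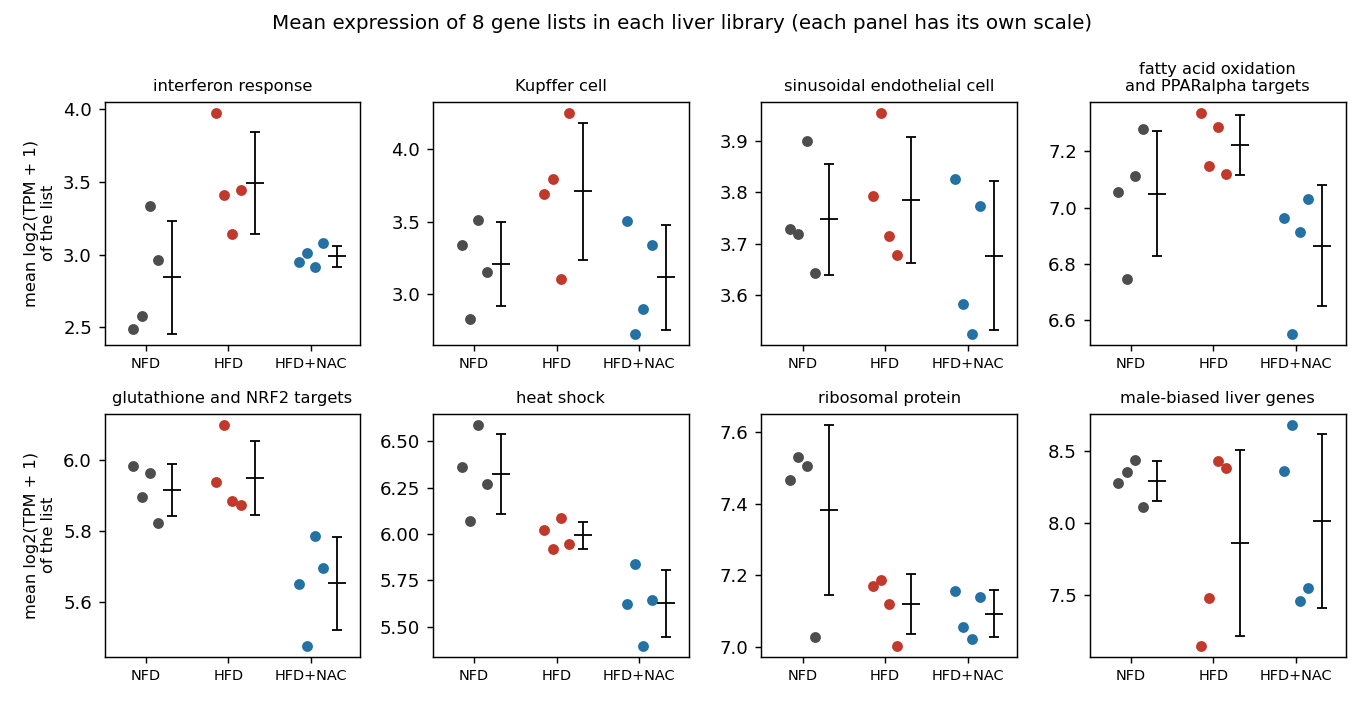
Mean log2(TPM + 1) of 8 gene lists in each of the 12 libraries, each panel on its own scale, with points for libraries and black marks for the mean ± SD of the 4 libraries of a group. The interferon mean spanned 3.14 to 3.98 in HFD and 2.91 to 3.08 in NAC_HFD, and the male-biased mean spanned 7.14 to 8.43 in HFD.

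Camera called no other list in HFD against NFD, while single members of some passed. Fry called 2 lists, adipose (adjusted p = 0.00861) and gut and gallbladder markers (adjusted p = 0.0182), the latter not called by camera. Xenobiotic metabolism genes (adjusted p = 0.0638) held Nr1i2, a nuclear receptor for foreign compounds (21.9 ± 4.17 to 34.9 ± 1.23 TPM, adjusted p = 0.00854), and Cyp2b9, which rose. The carboxylesterase Ces2a fell (100.2 ± 14.4 to 60.2 ± 6.51 TPM, adjusted p = 0.00959). Adjusted over the list alone 5 rose and 2 fell. Pericentral hepatocyte markers (adjusted p = 0.207) held Lect2, a secreted chemotactic protein, at 82.6 ± 9.57 and 164.9 ± 2.98 TPM (adjusted p = 3.24e-04). In glucose metabolism and insulin response (adjusted p = 0.565) the transcription factor Foxo1 rose (6.62 ± 1.15 to 10.7 ± 1.06 TPM, adjusted p = 0.0235) and Igfbp2 fell. The glutathione peroxidase Gpx1 rose (980.3 ± 133 to 1465 ± 55.0 TPM, adjusted p = 0.0185) as the 1 of 32 glutathione and NRF2 targets over all genes (list adjusted p = 0.439; 5 adjusted over the list alone). Abcg8, a sterol transporter (bile acid list, adjusted p = 0.207), Sult5a1 (periportal list, adjusted p = 0.827) and Fabp2 (gut and gallbladder list, adjusted p = 0.207) rose with adjusted p of 0.0450, 0.0499 and 0.0296. Without single libraries the calls of Foxo1, Gpx1, Abcg8, Sult5a1 and Fabp2 were lost in 5, 2, 8, 7 and 6 of 8 cases, with highest adjusted p of 0.0786 (HFD replicate 4), 0.0705 (HFD replicate 1), 0.123 (HFD replicate 1), 0.126 (NFD replicate 1) and 0.0886 (HFD replicate 2). Lipogenesis (adjusted p = 0.914), cholesterol synthesis (0.827), cysteine and methionine metabolism (0.908), endoplasmic reticulum stress (0.827), fibrosis (0.548), oxidative phosphorylation (0.439), mitochondrially encoded genes (0.827), cell cycle (0.299), immediate early (0.827), circadian (0.827) and glucocorticoid and metallothionein genes (0.827) were not called. Nor were markers of sinusoidal endothelial cells (0.827), stellate cells (0.439), cholangiocytes (0.455) or erythroid cells (0.859). The lipogenic genes Fasn (-0.41, adjusted p = 0.522), Scd1 (0.85, adjusted p = 0.511), Srebf1 (0.27, adjusted p = 0.697) and Elovl6 (-0.72, adjusted p = 0.401) of the fixed panel did not pass. Nor did Cyp7a1, the first enzyme of bile acid synthesis (-0.06, adjusted p = 0.947), Hmox1 (0.10, adjusted p = 0.891) or Nqo1 (0.29, adjusted p = 0.406). Scaling changed which genes were called and their split between directions. Median-of-ratios scaling gave 399 calls, 280 higher and 119 lower, of which 300 were shared with the 316. Quantile normalization gave 419, 259 higher and 160 lower, with 289 shared. Rescaling TPM within the gene table gave 287, 188 higher and 99 lower, with 254 shared.

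With N-acetylcysteine, the lipid and interferon genes that were high in HFD were lower on average, but no single gene passed the test against HFD. Both comparisons use the same HFD libraries, so genes named for being high in them tend toward a lower NAC_HFD mean by chance. Lgals1 was at 6.71 ± 3.44 TPM in NAC_HFD and 25.8 ± 6.99 TPM in HFD (log2 fold change -1.89, SE 0.36, adjusted p = 0.0599). Mogat1 was at 0.755 ± 0.297 and 2.90 ± 1.22 TPM (-1.11, SE 0.21, adjusted p = 0.0515) and Cd36 at 24.1 ± 13.1 and 63.3 ± 16.2 TPM (-1.45, SE 0.33, adjusted p = 0.0880). All 4 NAC_HFD libraries lay below all 4 HFD libraries in Lgals1 and Mogat1. Limma called 0 genes at an adjusted p of 0.05. There were 1870 at an unadjusted p under 0.05 (286 higher and 1584 lower with N-acetylcysteine, 568.8 of either direction expected by chance), 202 at an adjusted p under 0.1 and a smallest adjusted p of 0.0515. Groups did not overlap in 10.2% of genes, against 2.86% by chance. The count of 0 became 23 without HFD replicate 3, 64 without NAC_HFD replicate 1, 2 without NAC_HFD replicate 2 and 3 without NAC_HFD replicate 3, while array weights gave 157 and a block for replicate number 3. The median fold change of all genes was -0.08, and -0.01 with median-of-ratios scaling and 0.01 with quantile normalization, which both centre the genes. Male-biased genes ran in opposite order over replicates 1 to 4 in HFD and NAC_HFD (list means of 7.14, 7.48, 8.43 and 8.38 against 8.36, 8.68, 7.46 and 7.55). With HFD replicates 1 and 2 grouped with NAC_HFD replicates 3 and 4 against the rest, the grouping that an exchange of libraries would give, limma called 26 genes, with 1020 at an unadjusted p under 0.05. An exchange would change what the values of this comparison mean and was not settled, and handling in batches was not tested.

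Among the 50 smallest p, none of them past the threshold, the highest fold changes were those of Gpcpd1, a glycerophosphocholine phosphodiesterase (ENSMUSG00000027346, chromosome 2, 132529082 to 132578248; 0.90, SE 0.16, adjusted p = 0.0515), and Avpr1a, a vasopressin receptor (ENSMUSG00000020123, chromosome 10, 122448499 to 122453453; 0.83, SE 0.15, adjusted p = 0.0515). Then came Csrnp1 (ENSMUSG00000032515, chromosome 9, 119971163 to 119984742; 0.76, SE 0.15, adjusted p = 0.0570), Pih1d1 (ENSMUSG00000003423, chromosome 7, 45150613 to 45160065; 0.50, SE 0.10, adjusted p = 0.0599) and Hsd3b3 (ENSMUSG00000062410, chromosome 3, 98741476 to 98764540; 0.44, SE 0.09, adjusted p = 0.0599). Gpcpd1 was at 59.4, 56.5, 73.0 and 59.2 TPM in NAC_HFD and at 31.6, 24.2, 33.6 and 43.5 TPM in HFD. The lowest, beside Lgals1 and Mogat1 (ENSMUSG00000012187, chromosome 1, 78511060 to 78606964), were Acnat2, an acyltransferase (ENSMUSG00000060317, chromosome 4, 49374458 to 49408151; -1.45, SE 0.28, adjusted p = 0.0599), and the histone gene Hist1h3c (ENSMUSG00000069310; -1.06, SE 0.19, adjusted p = 0.0515). Next were Efna1, an ephrin (ENSMUSG00000027954, chromosome 3, 89271730 to 89280951; -0.98, SE 0.19, adjusted p = 0.0522), and Gas6, a ligand of TAM receptors (ENSMUSG00000031451, chromosome 8, 13465374 to 13494535; -0.96, SE 0.18, adjusted p = 0.0522).

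By list, interferon response genes were lower with N-acetylcysteine in 25 of 26 members (median -0.48; camera adjusted p = 6.78e-06, and adjusted p = 0.562 with an estimated correlation). Over all genes 0 passed in limma, and 11 fell when adjusted over the list alone. Among these were Ifi27l2a (7.51 ± 1.08 TPM in HFD and 3.08 ± 1.06 TPM in NAC_HFD), Zbp1 (11.6 ± 5.20 and 5.64 ± 1.30 TPM) and Igtp (34.8 ± 11.6 and 21.9 ± 1.39 TPM). The 4 list means per library of NAC_HFD, 2.91 to 3.08, lay below those of HFD, 3.14 to 3.98 (difference -0.50, exact permutation p = 0.0286, the smallest possible). Kupffer cell markers moved with them, lower in 13 of 14 members (median -0.71; adjusted p = 7.16e-04, and adjusted p = 0.562 with an estimated correlation) with 0 past the threshold in limma over all genes or adjusted over the list alone. Clec4f was at 15.7 ± 4.10 TPM and C1qa at 17.3 ± 5.11 TPM, against 27.8 ± 8.06 and 29.2 ± 8.75 TPM in HFD. Their list means per library overlapped (difference -0.59, exact permutation p = 0.114). Acute phase and inflammation genes were called lower (median -0.41; adjusted p = 0.0212, and adjusted p = 0.662 with an estimated correlation). Adjusted over the list alone 3 fell, among them Il1b (2.62 ± 0.905 and 0.812 ± 0.556 TPM) and Saa3 (17.9 ± 6.01 and 8.59 ± 1.27 TPM). That call was lost without HFD replicate 1, HFD replicate 4 or NAC_HFD replicate 3 (highest adjusted p = 0.392).

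Fatty acid oxidation genes and PPARalpha targets were lower with N-acetylcysteine in all 29 members (median -0.28; adjusted p = 9.71e-05, and adjusted p = 0.562 with an estimated correlation), 8 of them adjusted over the list alone. Fgf21, a hormone the liver secretes, was at 3.60 ± 1.10 TPM in HFD and 1.44 ± 0.748 TPM in NAC_HFD, and Vnn1 at 75.2 ± 11.6 and 44.5 ± 14.3 TPM. Glutathione and NRF2 targets were lower in 29 of 32 members (median -0.26; adjusted p = 6.21e-04, and adjusted p = 0.562 with an estimated correlation), 9 of them adjusted over the list alone. Thioredoxin (Txn1) was at 121.5 ± 13.4 and 76.5 ± 8.72 TPM (adjusted p = 0.0515). Nfe2l2, which encodes NRF2, was at 31.3 ± 2.44 and 23.4 ± 2.67 TPM (adjusted p = 0.0902), and the glutathione transferase Gstm4, which has close paralogs, at 22.8 ± 2.89 and 13.4 ± 4.24 TPM (adjusted p = 0.0727). Gclc (-0.14, adjusted p = 0.799), Gclm (-0.25, adjusted p = 0.458), Nqo1 (-0.63, adjusted p = 0.125) and Hmox1 (-0.68, adjusted p = 0.271) of the fixed panel did not pass. Endoplasmic reticulum and amino acid stress genes were lower in 19 of 23 members (median -0.39; adjusted p = 0.00313, and adjusted p = 0.562 with an estimated correlation). Adjusted over the list alone 11 fell, with the chaperones Hspa5 at 901.4 ± 46.3 and 526.1 ± 64.7 TPM and Hsp90b1 at 718 ± 47.1 and 486.6 ± 57.1 TPM. Adjusted in the same way 1 rose, Chac1, which degrades glutathione (1.46 ± 0.329 and 3.46 ± 1.08 TPM). Heat shock genes were called lower (median -0.31; adjusted p = 0.0139, and adjusted p = 0.562 with an estimated correlation), with 0 members in limma over all genes or adjusted over the list alone. That call was lost without HFD replicate 3 or NAC_HFD replicate 3 (highest adjusted p = 0.0683).

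Lipid droplet and fatty acid uptake genes were called lower in 21 of 25 members (median -0.28; adjusted p = 0.0210, and adjusted p = 0.562 with an estimated correlation). Mogat1 and Cd36 were the 2 that fell when adjusted over the list alone, and Cidec was at 10.6 ± 3.40 and 1.90 ± 1.20 TPM (adjusted p = 0.149 over all genes). The call was lost without HFD replicate 1, HFD replicate 4, NAC_HFD replicate 2 or NAC_HFD replicate 3 (highest adjusted p = 0.140). Cholesterol synthesis genes were called lower in 24 of 25 members (median -0.40; adjusted p = 0.0217, and adjusted p = 0.760 with an estimated correlation), with 0 members adjusted over the list alone. The squalene epoxidase Sqle was at 18.2 ± 14.0 and 5.84 ± 7.66 TPM. This call was lost without HFD replicate 1, HFD replicate 2, NAC_HFD replicate 1 or NAC_HFD replicate 2 (highest adjusted p = 0.382). Gut and gallbladder markers were called lower on 3 members (median -0.68; adjusted p = 0.0247, and adjusted p = 0.562 with an estimated correlation). Fabp2 and Lgals4 were the 2 that fell when adjusted over the list alone, and the call was lost without HFD replicate 1, NAC_HFD replicate 1 or NAC_HFD replicate 3 (highest adjusted p = 0.0582).

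The lists called higher with N-acetylcysteine relative to other genes had medians near 0 on the TPM scale. Periportal hepatocyte markers had a median of 0.15 (adjusted p = 0.00155, and adjusted p = 0.562 with an estimated correlation), with 9 of 14 positive. Adjusted over the list alone 1 member rose, the immunoglobulin receptor Pigr (581.7 ± 38.6 and 767.7 ± 61.0 TPM). Male-biased genes had a median of 0.17 with 16 of 22 positive (adjusted p = 0.00304, and adjusted p = 0.662 with an estimated correlation), and per library NAC_HFD was at 8.36, 8.68, 7.46 and 7.55 (exact permutation p = 0.657). Immediate early genes had a median of 0.07 (adjusted p = 0.0160, and adjusted p = 0.562 with an estimated correlation), with Ier2 and Gadd45g rising and 1 falling when adjusted over the list alone. Stellate cell markers had a median of 0.03 (adjusted p = 0.0217, and adjusted p = 0.662 with an estimated correlation). The median of glucose metabolism genes was -0.03, opposite in sign to the test (adjusted p = 0.0210, and adjusted p = 0.562 with an estimated correlation). Quantile normalization ended the calls of male-biased, immediate early and glucose genes (adjusted p = 0.341, 0.191 and 0.303). A floor of 5 TPM ended those of glucose metabolism and insulin response genes and hepatic stellate cell markers (adjusted p = 0.0531 and 0.0866), and left fewer than 3 gut and gallbladder markers, which were then not tested. Without single libraries the calls were lost for male-biased genes (HFD replicates 1 and 2, NAC_HFD replicates 1 and 2, highest adjusted p = 0.287) and immediate early genes (NAC_HFD replicate 3, 0.422). They were also lost for glucose genes (HFD replicate 1, NAC_HFD replicates 3 and 4, highest adjusted p = 0.162) and stellate markers (HFD replicate 1, NAC_HFD replicates 1 and 4, 0.322). Fry called 3 lists lower, glutathione and NRF2 targets (adjusted p = 0.0290), gut and gallbladder markers (0.00323) and cell cycle genes (0.0290), the last not called by camera. Lists not called by camera were monocyte-derived macrophages (adjusted p = 0.0723), mitochondrially encoded (0.0723), xenobiotic metabolism (0.0782), glucocorticoid and metallothionein (0.0976), ribosomal protein (0.209), bile acid (0.327) and cell cycle genes (0.327). Nor were lipogenesis (0.333), erythroid (0.378), oxidative phosphorylation (0.378), adipose (0.512), circadian (0.512), cholangiocyte (0.512), endothelial (0.552), pericentral (0.560), cysteine and methionine (0.650), fibrosis (0.804) or female-biased genes (0.885) called. The number of lists called, 15, was 8 without HFD replicate 1 and 9 without NAC_HFD replicate 3.

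**Figure D3:**
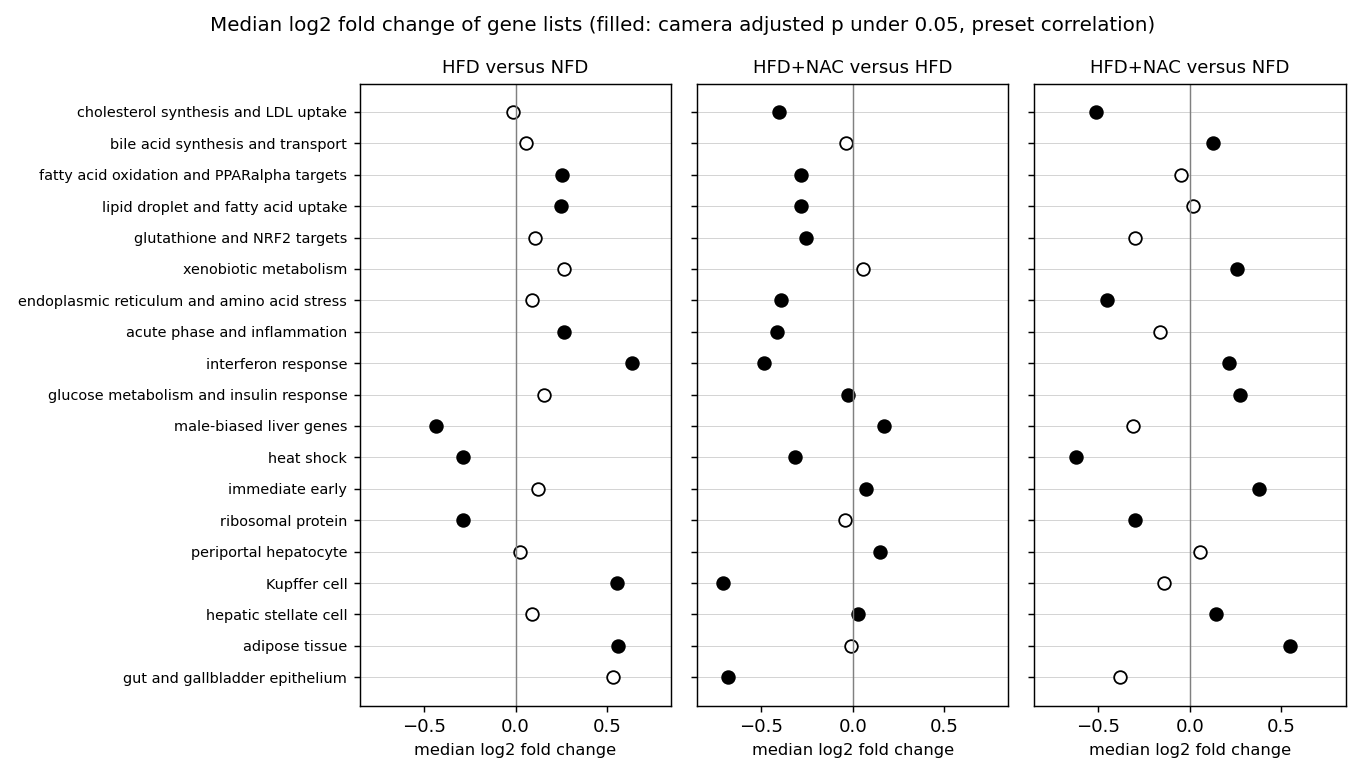
Median log2 fold change of the 19 gene lists called in at least 1 of the 3 comparisons, with filled points for a camera adjusted p under 0.05 with the preset correlation. The interferon median was 0.63 in HFD against NFD and -0.48 in NAC_HFD against HFD, and the heat shock median was -0.28, -0.31 and, in NAC_HFD against NFD, -0.62.

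Compared with the normal diet, NAC_HFD livers had less RNA of heat shock genes, while single metabolic enzymes were higher or lower. Heat shock genes were lower in 14 of 15 members (median -0.62; camera adjusted p = 1.01e-06, and adjusted p = 0.544 with an estimated correlation). Of them 9 were past the threshold over all genes and 12 adjusted over the list alone, and fry called this list alone (adjusted p = 0.0102). Hsph1 fell from 116.3 ± 17.5 to 59.8 ± 14.9 TPM (-0.97, SE 0.15, adjusted p = 0.00601). Bag3, a co-chaperone, fell from 45.3 ± 11.3 to 25.4 ± 2.88 TPM (-0.79, SE 0.15, adjusted p = 0.0118) and Hspa8 from 2197 ± 382 to 1306 ± 282 TPM (-0.76, SE 0.16, adjusted p = 0.0173). In each of these 3 genes all 4 NAC_HFD libraries lay below all 4 NFD libraries. Without NAC_HFD replicate 4 the adjusted p of Hspa8 was 0.0553. Of 11376 genes 601 passed in limma, 200 higher and 401 lower, and 548 of them did not overlap; across all genes 1369 of 11376 did not overlap, against 2.86% by chance. The split depended on scaling, with 357 higher and 280 lower after median-of-ratios scaling and 314 and 294 after quantile normalization. It was 183 and 496 with TPM rescaled within the gene table. The count was 252 without NFD replicate 1, 295 without NFD replicate 3, 243 without NAC_HFD replicate 3, 211 without NAC_HFD replicate 4 and 188 when only the 8 libraries of the comparison were fitted.

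The highest fold changes were those of Cyp2b9 (4.44, SE 0.77, adjusted p = 0.0158), Adgrv1 (2.06, SE 0.21, adjusted p = 4.69e-04), Upp2, a uridine phosphorylase (ENSMUSG00000026839, chromosome 2, 58566317 to 58795846; 1.64, SE 0.21, adjusted p = 0.00328). After these came Gpcpd1 (1.52, SE 0.16, adjusted p = 4.69e-04), Dio1, which activates thyroid hormone (ENSMUSG00000034785, chromosome 4, 107291465 to 107307168; 1.49, SE 0.16, adjusted p = 6.52e-04), and Dsg1c, a desmosomal cadherin (ENSMUSG00000034774, chromosome 18, 20247340 to 20285031; 1.43, SE 0.27, adjusted p = 0.0141). Gpcpd1 was at 21.1 ± 3.14 TPM in NFD, 33.2 ± 7.99 TPM in HFD and 62.0 ± 7.44 TPM in NAC_HFD, and Dio1 at 29.9 ± 7.43, 103.8 ± 11.96 and 84.5 ± 12.5 TPM. The lowest were Angptl8, a regulator of lipoprotein lipase (ENSMUSG00000047822, chromosome 9, 21835510 to 21837347; -2.52, SE 0.52, adjusted p = 0.0248), and the small heat shock gene Hspb1 (ENSMUSG00000004951, chromosome 5, 135887919 to 135889563; -2.03, SE 0.50, adjusted p = 0.0442). Then came Cyp4a31 (ENSMUSG00000028712, chromosome 4, 115563627 to 115579015; -1.60, SE 0.26, adjusted p = 0.00920) and Cyp2c69 (-1.55, SE 0.12, adjusted p = 6.12e-05). The other two were Hspa1b (ENSMUSG00000090877, chromosome 17, 34956429 to 34959238; -1.55, SE 0.36, adjusted p = 0.0335) and the tubulin gene Tubb2a (ENSMUSG00000058672, chromosome 13, 34074278 to 34078008; -1.53, SE 0.38, adjusted p = 0.0416). Angptl8 was at 147.8 ± 34.5 TPM in NFD, 51.6 ± 27.8 TPM in HFD and 29.2 ± 21.8 TPM in NAC_HFD. Without single libraries the calls of Hspb1, Hspa1b and Tubb2a were lost in 6 of 8 cases each (highest adjusted p = 0.0955 without NAC_HFD replicate 4, 0.0875 without NFD replicate 1 and 0.105 without NAC_HFD replicate 4) and that of Angptl8 in 4 (0.0694, without NAC_HFD replicate 3). Hspb1 was at 128 TPM in NFD replicate 3 and at 33.2 to 48.7 TPM in the other NFD libraries.

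Ribosomal protein genes were lower than in NFD in 26 of 27 members (median -0.30; adjusted p = 3.39e-05, and adjusted p = 0.726 with an estimated correlation). Their list means overlapped, since NFD replicate 4 was at 7.03 and NAC_HFD at 7.02 to 7.16 (exact permutation p = 0.114). Over all genes 2 fell, Rps19 (116 ± 12.8 to 82.0 ± 7.26 TPM, adjusted p = 0.0176) and Rps18 (265.9 ± 25.4 to 189.8 ± 15.9 TPM, adjusted p = 0.0231), and 12 when adjusted over the list alone. Rps19 was lost without NFD replicate 1 (adjusted p = 0.0511) and Rps18 without 4 of 8 libraries (highest 0.0671, without NAC_HFD replicate 4). Endoplasmic reticulum and amino acid stress genes were called lower (median -0.45; adjusted p = 0.0191, and adjusted p = 0.703 with an estimated correlation). Of them Hspa5, Hsp90b1 and Sdf2l1 fell (adjusted p = 0.0401, 0.0442 and 0.0485) and Chac1 rose (0.695 ± 0.546 to 3.46 ± 1.08 TPM, adjusted p = 0.00530). There were 8 that fell and 1 that rose when adjusted over the list alone. That list was lost without NFD replicate 1 or NFD replicate 2 (highest adjusted p = 0.0723), and its 3 falling genes without 6, 6 and 5 of 8 libraries (highest 0.106 without NAC_HFD replicate 3, 0.118 and 0.117 without NFD replicate 1). Cholesterol synthesis genes were called lower (median -0.51; adjusted p = 0.0313, and adjusted p = 0.978 with an estimated correlation), with 0 members in limma over all genes or adjusted over the list alone. That call was lost without NFD replicate 1, NFD replicate 4, NAC_HFD replicate 1 or NAC_HFD replicate 2 (highest adjusted p = 0.405). Of the glutathione and NRF2 targets (not called, adjusted p = 0.0763) 3 fell and 2 rose over all genes, and 7 fell and 2 rose adjusted over the list alone. Glutathione synthetase (Gss) fell from 30.5 ± 1.84 to 18.5 ± 2.36 TPM (adjusted p = 0.00960), Txnrd1 from 54.6 ± 7.03 to 38.1 ± 1.58 TPM (adjusted p = 0.0189) and Nfe2l2 from 31.8 ± 2.77 to 23.4 ± 2.67 TPM (adjusted p = 0.0294). Catalase (Cat) rose from 1359 ± 149 to 1822 ± 160 TPM (adjusted p = 0.0335). Txnrd1 was lost without NAC_HFD replicate 4 (0.0530), and Nfe2l2 and Cat without 6 of 8 libraries each (highest 0.0704 without NFD replicate 3 and 0.0957 without NAC_HFD replicate 4).

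Xenobiotic metabolism genes were called higher (median 0.26; adjusted p = 0.00277, and adjusted p = 0.703 with an estimated correlation), with 3 rising over all genes and 4 adjusted over the list alone. The 3 were Por, the reductase that serves cytochromes P450 (257.2 ± 29.0 to 422.6 ± 72.4 TPM, adjusted p = 0.00965), Nr1i2 (21.9 ± 4.17 to 33.2 ± 2.08 TPM, adjusted p = 0.0116) and Cyp2b9. Bile acid genes (median 0.13; adjusted p = 0.0281, and adjusted p = 0.703 with an estimated correlation) were called higher. They held the sterol transporters Abcg8 (20.6 ± 2.09 to 40.9 ± 12.5 TPM, adjusted p = 0.0118) and Abcg5 (22.3 ± 4.41 to 37.0 ± 8.98 TPM, adjusted p = 0.0247, lost without 4 of 8 libraries, highest 0.0651 without NAC_HFD replicate 4). Of the list, 4 rose and 2 fell when adjusted over the list alone. Glucose metabolism and insulin response genes were called higher (median 0.27; adjusted p = 0.0191, and adjusted p = 0.703 with an estimated correlation). Foxo1 rose (6.62 ± 1.15 to 14.1 ± 2.30 TPM, adjusted p = 0.00328), and adjusted over the list alone 2 rose and 3 fell. The insulin receptor substrate Irs1 and the gluconeogenic enzyme Fbp1 fell (adjusted p = 0.0375 and 0.0456, each lost without 6 of 8 libraries, highest 0.0931 without NFD replicate 3 and 0.0998 without NFD replicate 2). Stellate cell markers (median 0.14; adjusted p = 0.0115, and adjusted p = 0.703 with an estimated correlation) and immediate early genes (0.38; adjusted p = 0.0191, and adjusted p = 0.703 with an estimated correlation) were called higher. So were interferon genes (0.21; adjusted p = 0.0281, and adjusted p = 0.978 with an estimated correlation) and adipose markers (0.55; adjusted p = 0.0382, and adjusted p = 0.544 with an estimated correlation). Each of these 4 lists had 0 members past the threshold in limma over all genes or adjusted over the list alone.

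Of the 7 lists called higher, quantile normalization ended the calls of xenobiotic (adjusted p = 0.0759), bile acid (0.181), glucose (0.163), immediate early (0.0927), interferon (0.129) and adipose (0.163) genes. A floor of 5 TPM ended those of bile acid (adjusted p = 0.0513), glucose (0.0540) and interferon genes (0.135), and left too few adipose markers to test. Without single libraries, calls were lost for xenobiotic genes (NFD replicate 3, 0.0585), stellate markers (NFD replicate 2 and NAC_HFD replicate 1, highest 0.103). They were lost for immediate early and bile acid genes (NFD replicate 1 and NAC_HFD replicate 3 each, highest 0.184 and 0.165) and glucose genes (NFD replicate 1 and NAC_HFD replicate 3, highest 0.0723), and for interferon genes (NFD replicates 1 and 2 and NAC_HFD replicate 2, highest 0.488) and adipose markers (NFD replicates 1, 3 and 4 and NAC_HFD replicates 1 and 2, highest 0.0846). The 11 calls were 4 without NFD replicate 1. In lists that were not called, pericentral markers (adjusted p = 0.0874) had Lect2 (adjusted p = 0.00601), Gulo (0.00666) and the alcohol-metabolizing Cyp2e1 (6128 ± 658 to 9323 ± 502 TPM, adjusted p = 0.00816) higher. Periportal markers (adjusted p = 0.0575) had Pigr (0.00586) and Sult5a1 (0.0118) higher. Il1b (adjusted p = 0.0253), Icam1 (0.0493), Per2 (0.0243) and Dgat1, which makes triglycerides (0.0211), fell. Their calls were lost without 5, 7, 4 and 3 of 8 libraries (highest adjusted p = 0.0738 without NAC_HFD replicate 4, 0.127 without NAC_HFD replicate 3, 0.0590 and 0.0589 without NAC_HFD replicate 4). Other lists not called were glucocorticoid and metallothionein genes (adjusted p = 0.0904), mitochondrially encoded (0.1001), cholangiocyte (0.153), lipid droplet (0.274), erythroid (0.368), lipogenesis (0.538), male-biased (0.752), fibrosis (0.773) and acute phase genes (0.773). So were cysteine and methionine (0.849), gut and gallbladder (0.849), oxidative phosphorylation (0.921), fatty acid oxidation (0.921), circadian (0.921), monocyte-derived macrophage (0.921), Kupffer (0.921), cell cycle (0.921), female-biased (0.965) and endothelial (0.965). None of the 29 tested panel genes passed in this comparison.

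The design also asks whether changes with N-acetylcysteine oppose those of the diet. Of the 249 genes higher in HFD than in NFD, 226 had a lower mean in NAC_HFD than in HFD, and 218 had a NAC_HFD mean between those of NFD and HFD. Of the 67 genes lower in HFD, 45 were higher in NAC_HFD than in HFD. Both comparisons use the same HFD libraries, so genes picked for being extreme in HFD tend toward these signs by chance. Across the 11376 genes the covariance of the 2 fold changes was -0.0287, where the shared libraries alone gave -0.0152 and simulations with no effect gave -0.0152. The covariance had a jackknife error over libraries of 0.0154, and the excess of -0.0134 was smaller than that error. No error was computed for the excess itself. The excess was -0.00723 without HFD replicate 1, -0.0215 without HFD replicate 3, -0.00567 without HFD replicate 4 and -0.00754 without NAC_HFD replicate 2. With the HFD libraries split 2 and 2 so that none was used in both fold changes, the mean covariance of 6 splits was -0.0178 (-0.0224 to -0.0124).

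The genes called for HFD and for NAC_HFD against the normal diet overlapped. Among the genes called in both comparisons with NFD, 92 were higher in both and 38 lower in both, with 4.38 and 2.36 expected if the calls were independent, and 0 had opposite signs. They include Cyp2b9, Adgrv1, Nr1i2, Foxo1, Lect2, Abcg8 and Sult5a1, higher in both, and Cyp2c69, lower in both. The NFD libraries are shared, which raises such an overlap. With the NFD libraries split 2 and 2 so that the comparisons had separate controls the mean overlap of 6 splits was 14 higher (2 to 26) and 3 lower (1 to 9). The covariance of the 2 fold changes was 0.0517 against 0.0154 in simulations, and 0.0355 with separate controls.

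Few lncRNA transcripts passed the test. Gm30262 (XR_872040.2, chromosome 10, 111583051 to 111611588) was at 5.86, 4.88, 4.88 and 3.45 TPM in the HFD libraries, listed at 0 in 3 NFD libraries and at 0.75 TPM in the fourth, and listed at 0 in all 4 NAC_HFD libraries. It rose with the diet (log2 fold change 4.81, SE 0.60, adjusted p = 0.0247) and fell with N-acetylcysteine (adjusted p = 0.0105). A noncoding transcript of Hes1, a gene for a transcription factor (ENSMUST00000161676, chromosome 16, 30065357 to 30067796), was at 1.89, 1.29, 1.23 and 0.76 TPM in HFD and listed at 0 in the other 8 libraries (adjusted p = 7.68e-04 in both comparisons). Snhg1 (ENSMUST00000206383, chromosome 19, 8723487 to 8726326), annotated as a lncRNA gene like Gm30262 and a host of small nucleolar RNAs, fell with the diet from 47.3 ± 8.23 to 19.1 ± 0.992 TPM (-1.29, SE 0.18, adjusted p = 0.0351). The assembled MSTRG.1351.2 rose from 18.4 ± 5.001 to 53.8 ± 4.31 TPM (1.58, SE 0.21, adjusted p = 0.0319). The other diet calls were transcripts of Rapgef6 (NONMMUT009801.2, adjusted p = 0.0214, listed at 0 in NFD), Hacl1 (ENSMUST00000135751, adjusted p = 0.0319) and Col4a1 (ENSMUST00000130488, adjusted p = 0.00469), the last 2 listed at 0 in HFD and NAC_HFD. Against HFD, N-acetylcysteine raised a transcript of Ermard (ENSMUST00000227786; 0.108 ± 0.215 to 2.32 ± 0.442 TPM, adjusted p = 0.0151) and of Proscos (ENSMUST00000178990; 0.37, 0.33, 0.49 and 0.85 TPM, listed at 0 in the other 8 libraries, adjusted p = 0.0135). It lowered transcripts of Psme1 (ENSMUST00000173544, adjusted p = 0.0135) and Proscos (ENSMUST00000163731, adjusted p = 0.0498), both listed at 0 in NAC_HFD. The 2 Proscos transcripts belong to 1 gene, were low and offset each other. The one that fell was at 0.450 ± 0.152 TPM in NFD and 0.438 ± 0.210 TPM in HFD, the one that rose at 0.510 ± 0.237 TPM in NAC_HFD. A different division of reads between them cannot be told apart from a change of each.

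Of 25205 lncRNA transcripts tested, 7 passed for HFD against NFD (4 higher and 3 lower), 8 for NAC_HFD against HFD (2 and 6) and 25 for NAC_HFD against NFD (7 and 18). In these comparisons 2021, 2555 and 3343 had an unadjusted p under 0.05 where chance gives 1260. Groups did not overlap in 4.78%, 5.56% and 6.92% of them, against 2.86% by chance. Against NFD, NAC_HFD had higher transcripts of Cnot1 (ENSMUST00000211937, adjusted p = 0.0329), Oxr1 (NONMMUT023342.2, adjusted p = 0.0386) and Proscos (ENSMUST00000178990, adjusted p = 0.0162), all listed at 0 in NFD, and of Gpcpd1 (ENSMUST00000127712; 2.48 ± 0.536 to 9.82 ± 4.81 TPM, adjusted p = 0.0437). Lower were transcripts of Psme1 (adjusted p = 0.00364), Col4a1 (0.00469) and Rabggta (ENSMUST00000226209, 0.0296), listed at 0 in NAC_HFD, and Gm26917 (ENSMUST00000182520, 0.0302), which was at 1311, 519.43, 113.37 and 529.92 TPM in NFD and listed at 0 in 3 NAC_HFD libraries. Many of the transcripts named were low, and 77.3% of those tested come from genes of the gene table, so reads can be shared with the mRNA of the same gene. The median fold change of all lncRNA transcripts was -0.09, -0.11 and -0.19, and quantile normalization moved the last to 0.01. The 3 counts depended on single libraries. For the diet they were 3 without NFD replicate 3 or 4 or HFD replicate 1 or 3, 2 without HFD replicate 2 and 4 without HFD replicate 4. For NAC_HFD against HFD they were 4 without HFD replicate 1 or NAC_HFD replicate 4, 1 without HFD replicate 2 or 3, and 37 without NAC_HFD replicate 1. For NAC_HFD against NFD they were 6, 10, 2 and 3 without NFD replicates 1 to 4, 69 without NAC_HFD replicate 1 and 4 without NAC_HFD replicate 4. With transcripts above 0 in all 12 libraries alone, the counts were 0, 0 and 85.

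For mRNA the authors' deposited table held 1110 transcripts for HFD against NFD (696 higher and 414 lower, 277 with an adjusted p under 0.05) and 942 for NAC_HFD against HFD (452 and 490, 152 with an adjusted p under 0.05). For lncRNA the authors' deposited table held 789 (414 and 375, 84) and 1075 (423 and 652, 125). Of the authors' deposited tables, shares of 25.6% and 31.1% of the mRNA transcripts and 23.2% and 20.8% of the lncRNA transcripts were listed at 0 in every library of a group, where a fold change depends on how 0 was treated. The extreme log2 fold changes in the authors' deposited table of mRNA were transcripts of H2-Q7 (-21.85), Cyth1 (-21.05), BC031181 (22.76) and Cobll1 (24.50) for the diet, and Syvn1 (-24.60), Cobll1 (-24.48), H2-Q7 (22.36) and Kng1 (24.67) with N-acetylcysteine. For lncRNA the authors' deposited table had Son (-21.44), Pign (21.19) and Cnot1 (21.80), and Zfp687 (-21.90), Edrf1 (-8.94), Son (21.14) and Gm26608 (21.24). Of 248 mRNA transcripts in both comparisons of the authors' deposited table, 243 had opposite signs, 67 of them higher with the diet and lower with N-acetylcysteine and 176 the reverse. Of 183 lncRNA transcripts in both comparisons of the authors' deposited table, 178 had opposite signs. Both comparisons share the HFD libraries, which favours opposite signs among transcripts picked from both.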

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

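The splits of the libraries, the test without the most abundant genes and the test on the genes of highest TPM were chosen before the data were examined, and the 3 interferon tests, the splits at an unadjusted p and the rescaling within the gene table only after the result was seen. The split of the HFD libraries was planned, and its bound was changed after the result was seen.

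A Dixon test asked whether 1 library of a group stood far from the other 3. Over 198 groups 15 passed (7.58%), where chance gives 9.9. Cfd was at 0.58 TPM in NFD replicate 1, against 0.05 to 0.12 TPM, and at 32.7 TPM in HFD replicate 4, against 4.74 to 6.63 TPM. Hspb1 was at 128 TPM in NFD replicate 3, against 33.2 to 48.7 TPM, and at 25.5 TPM in HFD replicate 4, against 28.0 to 28.5 TPM. Saa1 was at 1936 TPM in HFD replicate 4, against 38.1 to 119 TPM in the other HFD libraries. In NFD replicate 2, Cib3 was at 5.52 TPM (others 2.49 to 2.92), Srebf1 at 27.4 TPM (12.7 to 14.7), Pdk4 at 1.57 TPM (0.93 to 0.99) and Efna1 at 23.5 TPM (15.6 to 16.0). In NAC_HFD replicate 2, Mogat1 was at 0.31 TPM (others 0.88 to 0.92) and Elovl6 at 21.7 TPM (12.2 to 12.8). Sqle was at 17.2 TPM in NAC_HFD replicate 4 (others 0.77 to 3.46), and Hist1h3c at 1.57 TPM in HFD replicate 3 (others 2.61 to 2.75). The lncRNA transcripts summed to 335620 TPM in HFD replicate 3 (others 351600 to 354730), and mitochondrially encoded genes took 8.91% of the gene table in HFD replicate 4 (others 11.01% to 11.4%).

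The libraries of each comparison were also split into 2 mixed sets of 4 in all 35 ways. For the genes of HFD against NFD only 1 split, the real one, gave 316 (highest other 4). For those of NAC_HFD against NFD only 1 gave 601 (highest other 15). Being alone is the strongest outcome that 35 splits allow, and it was read without adjustment for the number of counts. It argues against chance here without excluding it. For the genes of NAC_HFD against HFD the count could not decide, since the real count was 0 and all 35 splits had to give as many (highest other 26). At an unadjusted p under 0.05 the real split gave 1870 genes (highest other 1131). The split with 26 genes, HFD replicates 1 and 2 with NAC_HFD replicates 3 and 4 against the rest, points to a structure of the samples. For lncRNA transcripts chance could not be excluded with the diet, where 2 splits gave 7 or more (highest other 8). The real split alone gave the largest count for NAC_HFD against HFD (8 in the real split, 1 as large, highest other 4). The same held for NAC_HFD against NFD (25, 1 as large, highest other 6). With the same limit, chance was not excluded for these either, and both counts changed strongly with the processing, as given below. For gene lists chance could not be excluded in any comparison: 23, 3 and 14 splits gave at least the real 9, 15 and 11 lists, with highest others of 15, 16 and 17.

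Fold changes with N-acetylcysteine tended to oppose those of the diet, with a covariance of -0.0134 beyond that of the shared libraries. Chance could not be excluded, since 7 of 70 assignments of the libraries were as far below 0 (furthest other -0.0183). With separate HFD libraries for each fold change the mean covariance of 6 splits was -0.0178 (-0.0224 to -0.0124), below 0 in each. No HFD library entered both fold changes in these splits, so shared libraries do not make up these values. The mean was below 0 by less than 2 jackknife errors of the main covariance (0.0154), the bound set. That error belongs to the covariance without splits, and none was computed for the mean of the splits. Spread between animals therefore stays open as the source. That bound was made stricter, and a test after quantile normalization (excess -0.0147) was dropped, after these values were seen. That N-acetylcysteine reverses part of the diet response stays a hypothesis, to be tested with separate HFD animals for each comparison.

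Interferon genes were higher in HFD than in NAC_HFD, and this pattern was weighed in place of Kupffer markers after those were seen to overlap between groups (Kupffer minus endothelial mean 0.46 for the diet and -0.49 with N-acetylcysteine, exact permutation p = 0.114 each). A lower share of hepatocytes in HFD libraries would raise endothelial markers too. The interferon mean minus the endothelial mean differed by -0.40 between NAC_HFD and HFD (exact permutation p = 0.0286, the smallest possible). The nearest libraries, HFD replicate 3 at -0.5719 and NAC_HFD replicate 2 at -0.5740, hardly differed. For HFD against NFD the difference was 0.61 with overlap (exact permutation p = 0.0571). Scaling would be removed by quantile normalization, where the median was -0.39, and 1 HFD library would not leave -0.34 (SE 0.102) without HFD replicate 1, the value closest to 0. These tests argue against the 3 technical explanations as the whole source, for NAC_HFD against HFD alone. A part from the share of hepatocytes and a change in macrophages or other immune cells stay open. A lower interferon response with N-acetylcysteine is a hypothesis, to be tested by counting immune cells in the same livers.

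More genes were lower than higher in NAC_HFD against HFD, with a median of -0.08. Without the 100 most abundant genes the median was -0.0322, which cannot tell whether a few genes taking more of the TPM made the shift. Rescaling within the gene table left -0.0734, which argues against lncRNA transcripts outside that table and leaves those summed into its genes open, and the genes of highest TPM, of 3 equal sets, had -0.0695, which argues against a fall of low genes alone. Median-of-ratios scaling (-0.01) and quantile normalization (0.01) centre the genes by construction and do not decide, so the source of the shift stays open. A lower level of many RNAs with N-acetylcysteine is a hypothesis that needs RNA of known amount added to each sample.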

How the results depend on the processing

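Of the alternatives, rescaling within the gene table and keeping only lncRNA transcripts above 0 in all 12 libraries were chosen only after the result was seen. No called list and no named gene past the threshold changed direction in any setting run, but many counts were not stable, and the cause was not tested. For genes, the 316 of HFD against NFD became 168 with no filter, 884 with array weights, 52 at an absolute log2 fold change of 1 or more, and 90 (without HFD replicate 1) to 298 (without HFD replicate 3) without single libraries. The 0 of NAC_HFD against HFD became 3 with a replicate block, 157 with array weights and 0 to 64 (without NAC_HFD replicate 1). The 601 of NAC_HFD against NFD became 289 with no filter, 45 at that fold change, 188 on 8 libraries and 211 (without NAC_HFD replicate 4) to 618 (without NFD replicate 4). For lncRNA transcripts, the 7 of HFD against NFD became 2 with TPM of at least 1, 0 with values above 0 in all libraries, 1 with a block and 2 to 5 without single libraries. The 8 of NAC_HFD against HFD became 5 with no filter, 3 with TPM of at least 1, 5 with median-of-ratios scaling or quantile normalization, 0 above 0 in all, 1 with a block, 4 on 8 libraries and 1 to 37 without single libraries. The 25 of NAC_HFD against NFD became 16 on log2(TPM + 1), 3 with no filter, 79 with TPM of at least 1, 85 above 0 in all, 1 with a block, 13 on 8 libraries and 2 to 69 without single libraries. The 9, 15 and 11 gene lists became 0, 0 and 0 with an estimated correlation and 2, 3 and 1 with fry. They were 7 to 12, 8 to 16 and 4 to 16 without single libraries, and the 11 became 6 with quantile normalization. The covariance of -0.0287 became -0.0484 on log2(TPM + 0.1) and -0.0424 to -0.0220 without single libraries. Block, pseudocounts and scaling otherwise left the gene counts within 1.5 times.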

Other observations

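The tests of list means and of pathways and the splits at an unadjusted p here were chosen only after the result was seen.

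Some genes of tryptophan breakdown were higher in NAC_HFD than in NFD. Among the 200 genes higher in that comparison were 5 of the 10 tested genes of the KEGG tryptophan metabolism pathway, namely Afmid, Cat, Haao, Ido2 and Inmt, with 0.211 expected (Fisher test, adjusted p = 1.61e-04 over 182 pathways). The call of Cat was lost without 6 of 8 libraries (highest adjusted p = 0.0957, without NAC_HFD replicate 4). Steroid hormone biosynthesis had 6 of 38, namely Akr1c20, Cyp2b9, Cyp2e1, Hsd17b6, Hsd3b2 and Sult5a1, with 0.803 expected (adjusted p = 0.0111). For the genes higher in HFD than in NFD the smallest adjusted p was 0.130, with 6 of 41 genes of NOD-like receptor signaling (Gbp2, Gbp7, Ifi204, Ifi207, Ifi213 and Mndal). This test treats genes as independent, and genes of a pathway are often regulated together.

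Major urinary protein genes, which are higher in male than in female mouse liver, differed between libraries within the groups on the high fat diet. They took 12.3%, 11.4%, 11.5% and 11.04% of the gene table in NFD, 7.16%, 7.47%, 13.1% and 15.5% in HFD, and 14.4%, 15.1%, 8.14% and 7.02% in NAC_HFD. Male-biased genes had list means of 7.14, 7.48, 8.43 and 8.38 in HFD and 8.36, 8.68, 7.46 and 7.55 in NAC_HFD. Female-biased genes had 3.65, 3.65, 2.72 and 2.90 in HFD and 2.602, 2.597, 3.37 and 3.31 in NAC_HFD, against 2.50 to 2.71 in NFD. Replicates 1 and 2 thus stood apart from 3 and 4 in both groups, in opposite order, and the labels name no batch. Handling in batches was not tested. An exchange of libraries between HFD and NAC_HFD would change what every value of NAC_HFD against HFD means. The values below go both ways and do not settle it. At an unadjusted p under 0.05 the groups as named gave 1870 genes, and HFD replicates 1 and 2 with NAC_HFD replicates 3 and 4 against the rest gave 1020. At an adjusted p under 0.05 these groupings gave 0 and 26 genes, and 8 and 2 lncRNA transcripts. The Y-linked genes Kdm5d (4.39 to 8.52 TPM) and Uty (10.1 to 16.4 TPM) were present in all 12 libraries.

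As means per library, 6 lists were higher in all 4 HFD than in all 4 NFD libraries (exact permutation p = 0.0286 each, the smallest possible, adjusted p = 0.157), where chance gives 0.943 of 33 lists. They were lipid droplet (0.48), xenobiotic metabolism (0.46), female-biased (0.61), cell cycle (0.20), adipose (1.33) and gut and gallbladder genes (0.41). Single genes carry 2 of these means, Cyp2b9 (5.24) that of the 8 female-biased genes, of which 2 fell, and Cfd (3.03) that of the 3 adipose markers. With N-acetylcysteine 9 were lower than in HFD (adjusted p = 0.105), namely fatty acid oxidation (-0.36), lipid droplet (-0.48), glutathione and NRF2 (-0.30), endoplasmic reticulum stress (-0.45), interferon (-0.50), cell cycle (-0.22), heat shock (-0.37), adipose (-0.81) and gut and gallbladder genes (-0.69). Cfd (-2.46) carries the adipose mean, with a list median of -0.01. Against NFD, glutathione and NRF2 (-0.26), heat shock (-0.70) and gut and gallbladder genes (-0.28) were lower in NAC_HFD (adjusted p = 0.314).

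Among abundant lncRNA transcripts, NONMMUT042006.2 of Gm37350 was at 3430, 6094, 6735 and 10596 TPM in NAC_HFD, against 3012 to 3555 TPM in NFD and 3033 to 3941 TPM in HFD. ENSMUST00000192833 of Gm26917 was at 3137, 1931 and 315 TPM in NAC_HFD replicates 1 to 3 and listed at 0 in replicate 4. It was at 2871 to 3996 TPM in NFD and 2251 to 2905 TPM in HFD. Another transcript of Gm26917, NONMMUT029658.2, went the other way, at 1898, 2511, 2396 and 2666 TPM in NAC_HFD. That transcript was at 1598 to 1928 TPM in NFD and 1704 to 1998 TPM in HFD. How reads were divided between transcripts of this gene is not known, so a fall of the gene cannot be read from 1 of them.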
